A study of Homo sapiens
Mus musculus with 13 samples.

How the data were processed

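RNA from 4 mm spinal cord segments of 13 samples had been sequenced as stranded mRNA libraries with paired 150 bp reads. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.6.6 and quantified with Salmon 1.4.0. The genome build, the annotation release and the way mouse and human reads were told apart are not given in the sources used here. The deposited tables, 13 of mouse and 6 of human genes, hold expected counts (estimated reads per gene), TPM, and, per the file headers, a length and an effective length for each gene. The expected counts were rounded to whole numbers and used for every test, while the TPM values of the deposited tables were not used. Per the labels, the day 42 libraries were sequenced further and human transcripts were combined; human reads of day 14 are not analysed here. The transplantation day in the labels rises from 9 to 21 from sample to sample and was not used.

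There were 54270 names in each mouse table and 71157 in each human table, of which 70751 were kept after genes of the sex chromosomes that could identify a donor were left out. After edgeR's filterByExpr, 17917 mouse and 16030 human names were tested, and 1426 of the human names were Ensembl transcript identifiers in place of gene names. All 13 mouse tables were fitted together with 1 mean per day and treatment, and the 6 human tables in their own fit, by the edgeR quasi-likelihood method with TMM scaling (R 4.3.3, edgeR 4.0.16, limma 3.58.1). The comparisons were CNO against saline at day 14, at day 42 and averaged over days, the difference between the CNO effects of both days (interaction), day 42 against day 14 in saline and in CNO, and CNO against saline in the graft. Calls were made at a Benjamini-Hochberg adjusted p of 0.05 over all genes tested. Values per group are CPM after TMM scaling, as mean ± SD; fold changes are log2 ± SE, and a group without reads was set against a floor of 3 counts over the group. The floors cover counting error only, while the SE also covers the spread between samples.

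Gene lists of cell types and pathways, 37 for mouse and 24 for human, were written before the data were examined, as were the comparisons, the rule for named genes and the first set of alternatives. The 35 mouse and 22 human lists with at least 4 tested members were tested by camera with a preset correlation of 0.01 between genes. Camera with an estimated correlation and fry, which tests a list against no change and not against other genes, served as alternatives. Named genes were, among those past the threshold with a mean log2 CPM of at least 1, no overlap between groups and a regular gene name, the 10 largest changes in each direction. Where none passed, they were the 5 smallest p-values in each direction. Up to 4 members per list were also named, with 8 mouse and 7 human genes chosen in advance. Some list members that met this rule are not reported here, whatever their values; they stayed in every test and count. Shares of reads and totals per library were compared by two-sided exact permutation tests, within days for the average. The smallest p these can give is 0.1 for 3 against 3 and 0.0571 for 4 against 3 samples.

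Alternatives set in advance were DESeq2 1.42.0, its size factors in place of TMM, and no low-count filter. A stricter filter (1 CPM in at least 50% of samples and a mean of 5 counts), a fit of only the groups compared, and leaving out each library in turn were set in advance too. So were blocks by the replicate number or by the letter in the name of each deposited table. Alternatives added after the data were seen were leaving out the 3 libraries with under 12% of mouse reads on genes over 5000 bases, this share as a covariate, Salmon's effective length as an offset, graft entries with gene names only, graft lists with each table left out, and an estimated correlation in the list tests of these fits. A pseudocount alternative, meant for TPM, was not run because counts were deposited. The main fit of each comparison was tested on simulated data with 200 changed genes. The alternatives were not simulated. Between 64% and 87% of genes changed by 1 log2 unit and between 94% and 98% of those changed by 2 were called. Per comparison 5 to 13 unchanged genes were called. Genes were drawn independently and without the differences in library make-up reported below, so these rates need not hold for the real data. Other calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.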

Results

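Gene expression was measured by RNA sequencing at the epicentre of spinal cord injury in immunodeficient NOD-SCID mice. The mice carried a graft of neural stem and progenitor cells made from the human induced pluripotent stem cell line 414C2. One arm received intraperitoneal clozapine N-oxide (CNO, 5 mg/kg), the ligand of the designer receptors used for chemogenetic stimulation, and the other arm received saline. Segments 4 mm long were taken 14 days after injury (4 CNO samples, 3 saline samples) and 42 days after injury (3 CNO, 3 saline). Nothing in the labels says whether samples were separate animals, so the p-values measure the spread between these samples. All 13 samples had a table of mouse reads, which describes the host cord, and the 6 samples of day 42 also had a table of human reads, which describes the graft. Each mouse table held between 17.5 and 18.6 M reads in saline and between 19.7 and 20.9 M in CNO at day 14, and between 27.0 and 28.4 M in saline and between 31.2 and 35.0 M in CNO at day 42. The human tables held between 6.47 and 6.87 M reads in saline and between 6.65 and 7.73 M in CNO.

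The host libraries differed in the make-up of their reads. Genes longer than 5000 bases took 15.9% ± 0.882 (SD, n = 4) of host reads in CNO and 14.4% ± 2.48 (n = 3) in saline at day 14, and 16.3% ± 0.929 (n = 3) in CNO and 12.3% ± 2.84 (n = 3) in saline at day 42. The share was 2.78 percentage points higher in CNO averaged over both days (two-sided exact permutation within days, p = 0.0329). Of the 13 libraries, 3 lay below 12%: day 14 saline replicate 1 (11.8%), day 42 saline replicate 1 (11.9%) and day 42 saline replicate 2 (9.60%), and they are called the 3 low-share libraries from here on. Without them 2 saline libraries were left at day 14 and 1 at day 42, and this single library was assumed to vary like the other groups. Mitochondrial transcripts made up 8.24%, 9.19% and 15.7% of the reads of these libraries and between 5.23% and 7.21% of the reads of the other 10. On the first principal component of host expression (35.0% of the variance) the 3 low-share libraries lay between 41.7 and 74.4 and the other 10 between -35.2 and -0.518. The second component (18.6%) placed all 7 samples of day 14 above 0 and all 6 of day 42 below it. Depth was also higher in CNO, by 3.87 M reads averaged over days (two-sided exact permutation within days, p = 0.00143).

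**Figure D1:**
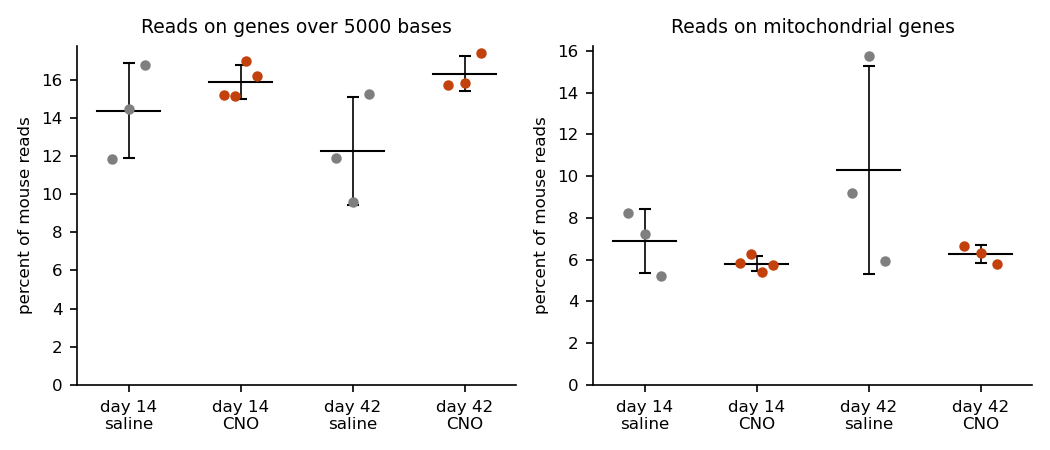
Percent of mouse reads on genes over 5000 bases (left) and on mitochondrial genes (right) in each host library, by day and treatment; dots are libraries, horizontal lines are group means and bars are the SD. Day 42 saline replicate 2 holds the lowest long-gene share (9.60%) and the highest mitochondrial share (15.7%).

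The first question was how the host cord differed between CNO and saline when both days were averaged. Neuronal transcripts stood higher and transcripts of microglia, macrophages and antigen presentation stood lower in CNO cords. With an estimated correlation camera set no list apart (adjusted p from 0.471). Among the genes that rose were the vesicular glutamate transporter Slc17a7 (log2 1.06 ± 0.27, SE, larger at day 14 than at day 42), the sodium channel Scn2a (0.72 ± 0.17) and the synaptic calcium sensor Syt1 (0.53 ± 0.12). Among those that fell were the phagocyte receptor Trem2 (-0.60 ± 0.11), the class I antigen-presenting molecule H2-K1 (-0.54 ± 0.10) and its light chain B2m (-0.57 ± 0.13), with edgeR adjusted p-values of 0.0480 to 0.0484 for all 6. These changes ran with the make-up of the libraries: all 3 low-share libraries were saline samples. In total 523 genes rose and 872 fell of 17917 tested by edgeR's quasi-likelihood test, with adjusted p-values from 0.0467 upwards, and 42 of these 1395 genes changed by more than 1 log2 unit.

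Every member tested was higher in CNO in 5 lists of neuronal genes fixed before the data were examined. They were presynaptic release (16 genes, median log2 0.49), postsynaptic scaffold and adhesion (15, 0.40), voltage-gated ion channels (13, 0.72), glutamate receptors and transport (12, 0.60), and GABA and glycine signalling (12, 0.64). Camera, which compares a list with all other genes, gave adjusted p-values of 2.5e-07, 2.5e-07, 9.8e-07, 1.8e-06 and 4.2e-06, and with an estimated correlation the adjusted p was 0.471 for each. Past the edgeR threshold over all genes were 3, 4, 3, 5 and 4 members, and past it adjusted over the list alone were 16, 14, 12, 11 and 10. By fry, which compares a list with no change, all 5 passed (adjusted p from 0.0311 to 0.0429). Single members that rose included Syn2 (0.43 ± 0.11), which clusters synaptic vesicles, the kinase Camk2a (0.59 ± 0.15), the scaffold Dlg2 (0.61 ± 0.17), the calcium channel Cacna1b (0.72 ± 0.20), the AMPA receptor subunit Gria2 (0.54 ± 0.13) and the GABA-making enzyme Gad1 (0.50 ± 0.13). In the list of neuronal cytoskeleton and identity, 11 of 12 members were positive (median 0.39, camera adjusted p = 0.000357, 0.486 with an estimated correlation). Of these only Elavl4 (0.51 ± 0.10), a neuronal RNA-binding protein, passed over all genes, and 5 passed adjusted over the list alone. The neuronal nuclear antigen Rbfox3 had a log2 of 0.54 ± 0.16 (edgeR adjusted p = 0.0518). The 3 low-share libraries had 34.6, 44.5 and 62.5 CPM of Rbfox3, the other 3 saline libraries 54.5, 75.2 and 76.4, and the 7 CNO libraries 72.4 to 93.8. Without the 3 low-share libraries the medians of the 5 lists above were 0.21, 0.16, 0.24, 0.26 and 0.29, with camera adjusted p-values from 5.1e-09 to 5.1e-06 and no member past the edgeR threshold. With the long-gene share as a covariate they were 0.15, 0.11, 0.15, 0.13 and 0.19 (1.8e-05 to 0.000827), again with no member past it.

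Of the immune lists, 4 stood lower in CNO. All 12 members of the MHC and antigen presentation list were negative (median -0.44, camera adjusted p = 4.2e-06, 0.471 with an estimated correlation), and 6 of them fell, H2-D1 (-0.43 ± 0.08) and the immunoproteasome subunit Psmb9 (-0.50 ± 0.12) among them. In the list of phagocytic macrophages and lipid handling, 15 of 16 members were negative (median -0.41, camera adjusted p = 6.9e-05, 0.471 with an estimated correlation). Its 6 falling members included the lipase Lpl (-0.49 ± 0.11), the lipid carrier Apoe (-0.48 ± 0.12) and the lysosomal tetraspanin Cd63 (-0.48 ± 0.13). All 10 genes of homeostatic microglia were negative (median -0.33, camera adjusted p = 0.000114, 0.471 with an estimated correlation), and 3 of them fell, Cx3cr1 (-0.40 ± 0.09) and P2ry12 (-0.33 ± 0.07) among them. Of 10 complement genes 5 fell, among them C1qa (-0.51 ± 0.13), C1qc (-0.47 ± 0.11) and C5ar1 (-0.47 ± 0.11), with a camera adjusted p of 0.00692 for the list and 0.471 with an estimated correlation. Adjusted over the list alone, 10, 12, 8 and 5 members of these 4 lists passed, and all 4 differed from no change by fry (adjusted p from 0.0178 to 0.0345). The interferon response (median 0.03, camera adjusted p = 0.565) and cytokines (-0.19, 0.111) were not set apart. Aif1, the microglial calcium-binding protein, had a log2 of -0.62 ± 0.18 (edgeR adjusted p = 0.0510). It was measured at 35.5 to 56.4 CPM in the 3 low-share libraries and at 24.4, 25.7 and 36.0 CPM in the other 3 saline libraries, against 21.1 to 29.1 CPM in CNO. Without the 3 low-share libraries the medians of the 4 lists were -0.31, -0.20, -0.29 and -0.28, with camera adjusted p-values from 7.5e-09 to 3.4e-05 and no member past the edgeR threshold. With the covariate they were -0.30, -0.16, -0.21 and -0.19 (6.5e-09 to 0.000262), again with no member past it.

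Other groups below the rest of the genes in CNO were oligodendrocyte progenitor (9 of 10 negative, median -0.27, camera adjusted p = 0.00129), proliferation (12 of 12, -0.36, 0.00103), ependymal and cilia genes (9 of 10, -0.41, 0.00692), myelin (12 of 12, -0.25, 0.00692) and fibrotic scar genes (14 of 14, -0.25, 0.0280). With an estimated correlation their adjusted p-values were 0.471, 0.471, 0.517, 0.663 and 0.696, and the first 3 differed from no change by fry (0.0178, 0.0311 and 0.0463). The genes that fell in them were C1ql1 (-0.57 ± 0.12), Enpp6 (-0.37 ± 0.09) and Sox10 (-0.29 ± 0.08) of the progenitor list, the centromere histone Cenpa (-0.59 ± 0.11), and the cilia genes Rsph1 (-0.57 ± 0.15), Foxj1 (-0.32 ± 0.09) and Spef2 (-0.44 ± 0.12). Adjusted over the list alone, 7, 6, 4, 0 and 0 members passed. Mbp, the main myelin protein gene, had a log2 of -0.43 ± 0.16 (edgeR adjusted p = 0.0745) and was highest in the low-share library day 42 saline replicate 2 (27012 CPM). Of the mitochondrially encoded transcripts all 12 were negative (median -0.57, camera adjusted p = 0.00323, 0.663 with an estimated correlation), mt-Co2 fell (-0.92 ± 0.23), and 11 passed adjusted over the list alone. Without the 3 low-share libraries the median of that list was -0.01 (camera adjusted p = 0.726), that of myelin -0.04 (0.639) and that of ependymal genes -0.16 (0.0664). With the long-gene share as a covariate they were 0.12 (0.101), 0.00 (0.865) and -0.12 (0.0510). Skeletal muscle genes (9 of 10 positive, median 2.16, camera adjusted p = 0.00815) and neutrophil genes (10 of 10, 0.69, 0.0482) stood higher with no member past the edgeR threshold or adjusted over the list alone. Their adjusted p-values with an estimated correlation were 0.663 and 0.734. The neutrophil median was 0.04 (camera adjusted p = 0.719) without the 3 low-share libraries and -0.09 (0.865) with the covariate.

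The genes that rose most, with no overlap between groups at either day, were Gpr165 (1.10 ± 0.31), the hyaluronan synthase Has3 (0.95 ± 0.21), Fbxo40 (0.91 ± 0.22), Thsd7b (0.90 ± 0.16), Frem3 (0.87 ± 0.22), Nwd2 (0.78 ± 0.17) and the synaptic scaffold Cnksr2 (0.75 ± 0.19). With them rose Lhx1 (0.86 ± 0.19), Pax2 (0.80 ± 0.22) and Pax8 (0.76 ± 0.11), transcription factors of dorsal spinal interneurons. Those that fell most were the mitochondrial leucyl-tRNA synthetase Lars2 (-1.04 ± 0.26), mt-Co2, the calcium-binding protein S100a4 (-0.87 ± 0.18), F9 (-0.81 ± 0.16), Msx2 (-0.79 ± 0.21), the macrophage folate receptor Folr2 (-0.75 ± 0.17), Ctla2b (-0.70 ± 0.15), Susd3 (-0.67 ± 0.12), AU020206 (-0.66 ± 0.13) and Smagp (-0.66 ± 0.15). Their edgeR adjusted p-values lay between 0.0467 and 0.0497. Of 18 immediate early genes, which neurons switch on after activity, 13 were negative and the list did not stand apart (camera adjusted p = 0.156). Ier2 (-0.65 ± 0.11), Junb (-0.51 ± 0.11) and Egr2 (-0.34 ± 0.09) fell, and without the 3 low-share libraries the list stood lower (median -0.18, camera adjusted p = 0.000115, 0.212 with an estimated correlation), and with the long-gene share as a covariate as well (-0.20, 2.9e-06, 0.0418). Over all libraries it differed from no change by fry (adjusted p = 0.0463) and had a camera adjusted p of 0.626 with an estimated correlation. Fos had a log2 of -0.19 ± 0.10 (edgeR adjusted p = 0.189) and Arc of 0.07 ± 0.07 (0.529). Values for the other genes followed throughout were -0.01 ± 0.11 for the neurotrophin Bdnf, -0.13 ± 0.09 for the astrocyte filament Gfap and -0.27 ± 0.35 for the collagen Col1a1 (edgeR adjusted p = 0.957, 0.277 and 0.587). The count of 1395 fell to 13 (1 higher, 12 lower) with DESeq2's size factors in place of TMM and to 0 without the 3 low-share libraries, while DESeq2's own test gave 4160. Leaving out 1 library gave 6725 genes without day 42 saline replicate 3, 5427 without day 14 saline replicate 3, 1 without day 14 CNO replicate 3, and 0 without each of the other 10.

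**Figure D2:**
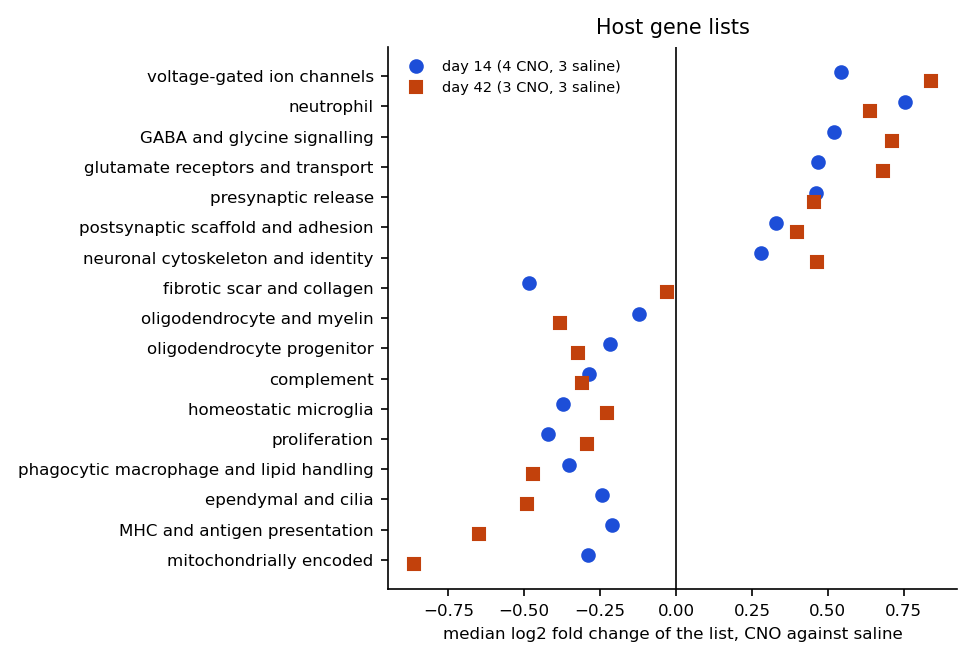
Median log2 fold change, CNO against saline, of the host gene lists set apart by camera over both days (skeletal muscle left out for scale), at day 14 (circles, 4 CNO and 3 saline samples) and day 42 (squares, 3 and 3). Presynaptic genes had medians of 0.46 and 0.45, MHC genes -0.21 and -0.65, and mitochondrially encoded genes -0.29 and -0.86.

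At day 14 alone, no single host gene passed between CNO and saline. Lists stood apart by camera with a preset correlation, and 0 of them passed with an estimated correlation or by fry. Presynaptic release genes were higher in CNO (16 of 16 positive, median log2 0.46) and homeostatic microglia genes lower (10 of 10 negative, median -0.37). Members with the smallest p-values were the syntaxin Stx1a (0.53 ± 0.12) and Slc17a7 (1.95 ± 0.40) on one side and P2ry12 (-0.44 ± 0.10) and Trem2 (-0.58 ± 0.15) on the other. edgeR called 0 of 17917 genes, with 2479 at an unadjusted p below 0.05 and a smallest adjusted p of 0.233; DESeq2 called 111. Camera set 17 lists apart, 9 higher and 8 lower, and none of them with an estimated correlation (adjusted p from 0.435) or by fry (from 0.172). Higher besides presynaptic release (camera adjusted p = 2.9e-08) were postsynaptic (3.5e-06), glutamate (3.9e-05), neuronal cytoskeleton (0.000117), ion channel (0.000117), GABA and glycine (0.000223), cholesterol synthesis (0.000187), muscle (1.8e-06) and neutrophil genes (0.0454). Lower were homeostatic microglia (1.0e-05), proliferation (8.1e-05), fibrotic scar (0.000117), phagocyte (0.000223), MHC (0.000659), complement (0.000920), oligodendrocyte progenitor (0.00142) and immediate early genes (0.0454). Adjusted over the list alone, members passed in presynaptic release (5), glutamate (2), microglia (6), complement (5), MHC (2), proliferation (1), phagocytes (1) and skeletal muscle (9). Of the 17 lists 16 were set apart in the same direction without the 3 low-share libraries, and the same 16 with the covariate; neutrophil genes were not (camera adjusted p = 0.940 and 0.372). Medians shrank from 0.54 to 0.31 and 0.20 for ion channels, from 0.52 to 0.29 and 0.27 for GABA and glycine, from 0.47 to 0.28 and 0.21 for glutamate, from 0.46 to 0.32 and 0.28 for presynaptic release, from 0.33 to 0.20 and 0.18 for postsynaptic genes and from -0.35 to -0.18 and -0.18 for phagocytes. Muscle genes differed between libraries of one group: the actin Acta1 was at 31.8, 3.15, 19.6 and 320 CPM in the 4 CNO libraries and at 0.609, 4.78 and 6.52 CPM in saline.

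The smallest p-values at day 14, none past the threshold, belonged to Celf6 (0.76 ± 0.13), Pax8 (0.91 ± 0.16), the neurite growth gene Nrn1 (0.64 ± 0.12), Cpne5 (0.79 ± 0.15) and the synaptic calcium-binding gene Doc2a (0.59 ± 0.11) among positive values. Among negative values they belonged to the thromboxane synthase Tbxas1 (-0.56 ± 0.10), Fgd2 (-0.45 ± 0.08), Gstp2 (-2.24 ± 0.40), Dok1 (-0.63 ± 0.11) and Amz1 (-0.42 ± 0.08), all with an edgeR adjusted p of 0.233. Gstp2 has a near-identical neighbour, Gstp1, and its counts are uncertain. Fos (-0.11 ± 0.14), Arc (0.11 ± 0.10), Bdnf (-0.17 ± 0.15), Rbfox3 (0.50 ± 0.23), Gfap (-0.06 ± 0.12), Mbp (-0.20 ± 0.22), Aif1 (-0.54 ± 0.25) and Col1a1 (-0.60 ± 0.48) had edgeR adjusted p-values from 0.359 to 0.804. Leaving out 1 library gave 0 to 5 genes, with 5 without day 14 saline replicate 3, 1 without each of CNO replicates 2, 3 and 4, and 0 without the others.

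At day 42 alone, again no host gene passed the test. Of 15 lists set apart by camera with a preset correlation, 0 passed with an estimated correlation, 1 by fry and 2 with the long-gene share as a covariate. Voltage-gated channels (13 of 13 positive, median log2 0.84) and GABA and glycine genes (12 of 12, 0.71) stood higher in CNO, and MHC genes (12 of 12 negative, -0.65) and mitochondrially encoded genes (12 of 12, -0.86) lower. Members with small p-values in these lists included Scn2a (0.89 ± 0.25), H2-D1 (-0.51 ± 0.12) and mt-Co2 (-1.24 ± 0.34). edgeR called 0 of 17917 genes, with 5480 at an unadjusted p below 0.05 and a smallest adjusted p of 0.114; DESeq2 called 1398. Camera set 15 lists apart, 6 higher and 9 lower, none with an estimated correlation (adjusted p from 0.614) and 1 by fry, MHC (adjusted p = 0.0377). Camera adjusted p-values were 1.4e-06 for ion channels, 1.6e-06 for postsynaptic genes, 4.4e-06 for GABA and glycine, 8.8e-06 for glutamate, 4.0e-05 for presynaptic release and 0.00611 for neuronal cytoskeleton on the higher side. On the lower side they were 1.6e-06 for MHC, 0.000307 for phagocytes, 0.000973 for mitochondrially encoded, 0.00289 for myelin, 0.00580 for oligodendrocyte progenitor, 0.00611 for microglia, 0.00736 for ependymal, 0.0116 for cholesterol synthesis and 0.0298 for proliferation. Adjusted over the list alone, 11 channel, 11 MHC, 11 mitochondrially encoded, 9 glutamate, 9 phagocyte, 7 myelin, 6 progenitor, 5 GABA and glycine and 5 ependymal genes passed. Of the 3 saline libraries, 2 were low-share libraries, and without the 3 low-share libraries, with 1 saline library left, 9 of the 15 lists were set apart in the same direction. Mitochondrially encoded (median 0.06, camera adjusted p = 0.607), myelin, progenitor, ependymal, neuronal cytoskeleton and proliferation genes were not. With the long-gene share as a covariate only 2 of the 15 were, MHC (median -0.36, camera adjusted p = 3.3e-09) and phagocytes (-0.13, 0.0139). The medians of ion channels, presynaptic and postsynaptic genes were then 0.04, 0.04 and 0.02 (0.226, 0.786 and 0.618), and that of mitochondrially encoded genes was 0.16 (0.0888), positive in place of negative.

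The smallest p-values at day 42 belonged to Rabgap1l (0.45 ± 0.09), Plppr5 (0.48 ± 0.10), Ccser1 (0.87 ± 0.18), Dzip3 (0.54 ± 0.11) and Zkscan8 (0.41 ± 0.09) among positive values. Among negative values they belonged to the growth factor Pdgfb (-0.46 ± 0.08), Copz2 (-0.70 ± 0.13), the inflammatory transcription factor Cebpb (-0.81 ± 0.15), the microglial nucleotide receptor P2ry6 (-0.53 ± 0.10) and Smad6 (-0.75 ± 0.14), all with an edgeR adjusted p of 0.114. Fos (-0.26 ± 0.15), Arc (0.02 ± 0.11), Bdnf (0.15 ± 0.15), Rbfox3 (0.58 ± 0.24), Gfap (-0.20 ± 0.13), Mbp (-0.66 ± 0.23), Aif1 (-0.71 ± 0.26) and Col1a1 (0.05 ± 0.52) had edgeR adjusted p-values from 0.117 to 0.954. Without day 42 saline replicate 3, the saline library with the highest long-gene share, 5688 genes passed; leaving out any other library gave 0. Across genes, the fold changes of CNO at day 14 and at day 42 had a Pearson r of 0.369 and a Spearman rho of 0.577, and 73.8% of genes had the same sign; genes are not independent replicates.

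Whether the CNO difference itself changed between the days was tested as an interaction. Genes of cholesterol synthesis had the smallest p-value of the lists: all 14 had a lower CNO against saline difference at day 42 than at day 14 (median -0.46), with the sterol enzymes Dhcr7 (-0.60 ± 0.16) and Fdps (-0.75 ± 0.22) holding the smallest p-values. Their median was 0.22 at day 14 and -0.25 at day 42. No single gene passed: edgeR called 0 of 17917, with 901 at an unadjusted p below 0.05, and DESeq2 called 11. Camera set 11 lists apart (1.9e-10 for cholesterol synthesis) and none with an estimated correlation (adjusted p from 0.839) or by fry (from 0.795); adjusted over the list alone, 5 cholesterol genes passed. Muscle (median -3.89), oxidative phosphorylation (-0.23), MHC (-0.34), heat shock (-0.15), mitochondrially encoded (-0.62), regeneration (-0.26) and myelin genes (-0.28) were also on the negative side, with camera adjusted p-values from 1.1e-05 to 0.0212. Fibrotic scar (0.49), ion channel (0.32) and GABA and glycine genes (0.18) were on the positive side (0.00477 to 0.0160). Of the 11 lists 4 were set apart in the same direction without the 3 low-share libraries: cholesterol synthesis (median -0.39, camera adjusted p = 3.6e-14), muscle, oxidative phosphorylation and heat shock. With the covariate they were cholesterol synthesis (-0.36, 6.2e-08), muscle, oxidative phosphorylation and fibrotic scar. Presynaptic release genes, with a median of 0.02 (0.932) over all libraries, stood lower at day 42 without those libraries (-0.18, 0.000427) and with the covariate (-0.25, 0 of 16 positive, 7.0e-06). Postsynaptic genes had medians of 0.14 (0.138), -0.09 (0.239) and -0.19 (0.00439) in the same order. No list was set apart with an estimated correlation in either setting (adjusted p from 0.893).

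The smallest interaction p-values belonged to Gstp2 (2.95 ± 0.58), Zfp300 (1.19 ± 0.25), the alarmin Il33 (0.45 ± 0.11), Foxp2 (0.92 ± 0.23) and Zkscan8 (0.49 ± 0.12) among positive values. Among negative values they belonged to Tmem158 (-1.002 ± 0.17), the neuropeptide Cartpt (-1.53 ± 0.27), the postsynaptic calmodulin-binding gene Nrgn (-1.15 ± 0.25), Trim36 (-0.53 ± 0.12) and the sensory neuron sodium channel Scn10a (-12.33 ± 3.04), with edgeR adjusted p-values of 0.693 for Tmem158 and Cartpt and 0.905 for the rest. Scn10a was at 19.6, 3.70, 8.22 and 0.0494 CPM in the 4 CNO libraries of day 14 and at 4.02 CPM in day 42 saline replicate 2. Fos (-0.15 ± 0.20), Arc (-0.10 ± 0.15), Bdnf (0.32 ± 0.21), Rbfox3 (0.08 ± 0.32), Gfap (-0.14 ± 0.17), Mbp (-0.46 ± 0.32), Aif1 (-0.17 ± 0.36) and Col1a1 (0.65 ± 0.70) had edgeR adjusted p-values from 0.905 to 0.977. Without day 42 saline replicate 3 the count was 3, and without day 14 CNO replicate 2 it was 1.

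The comparison of day 42 with day 14 in saline describes the injured host cord without CNO. Per the labels only the day 42 libraries were sequenced further. Time after injury and sequencing therefore cannot be told apart, here or in CNO. Members of the collagen, cell division and proteoglycan lists fell and genes of class II antigen presentation rose. With an estimated correlation camera set no list apart (adjusted p from 0.231). The scar collagens Col3a1 (log2 -3.18 ± 0.48, 542 ± 253 to 59.6 ± 17.2 CPM, SD, n = 3 each) and Col1a1 (-3.15 ± 0.56, 509 ± 279 to 57.2 ± 15.8 CPM) fell, and the class II invariant chain Cd74 rose (1.82 ± 0.16, 78.7 ± 10.6 to 278 ± 55.0 CPM). The injury-induced neuronal gene Sprr1a fell from 77.6 ± 5.83 to 9.19 ± 1.77 CPM (-3.08 ± 0.18, edgeR adjusted p = 4.8e-06). In total 153 genes rose and 315 fell of 17917 by edgeR, and 194 of these 468 changed by more than 1 log2 unit.

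**Figure D3:**
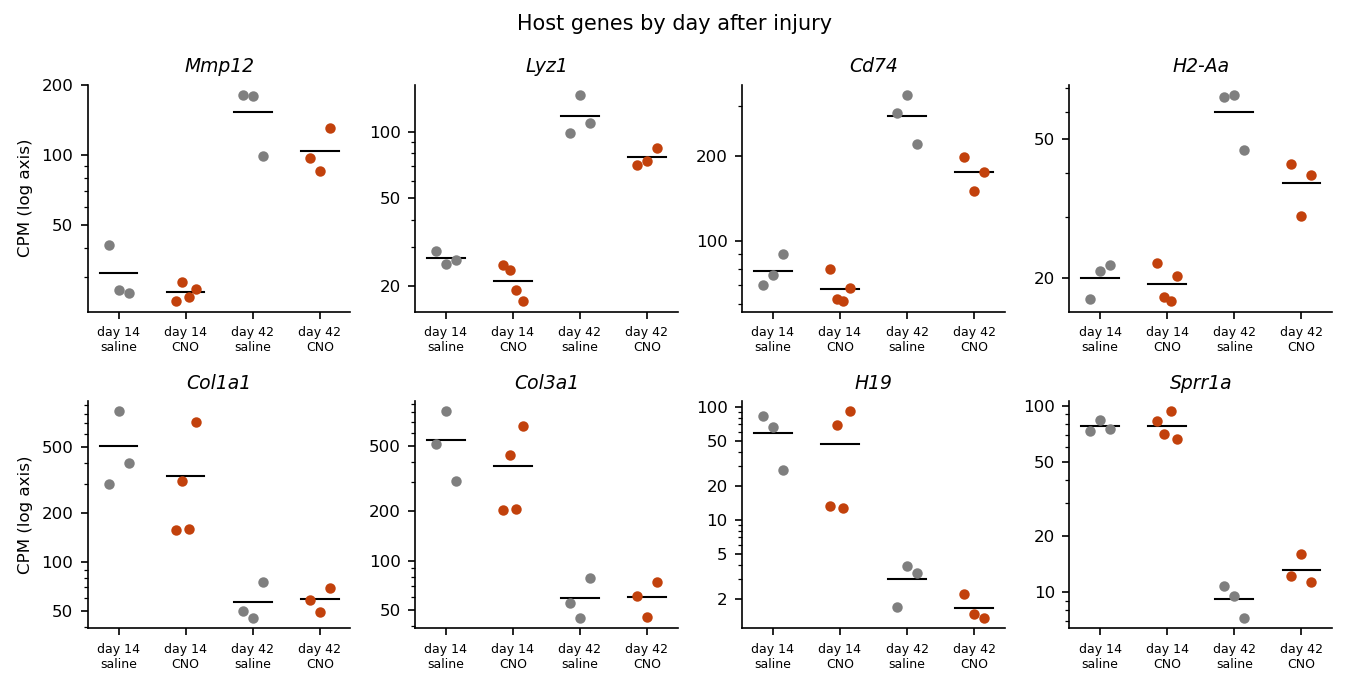
CPM on a log axis of 8 host genes in each library, by day after injury and treatment; dots are libraries and lines are group means. Mmp12 rose from 31.1 to 154 CPM in saline and from 25.8 to 105 in CNO, and Sprr1a fell from 77.6 to 9.19 in saline.

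In saline, the list of fibrotic scar and collagen genes had 13 of 14 members negative (median -1.16, camera adjusted p = 1.6e-11, 0.307 with an estimated correlation). Of these 9 fell, Col6a1 (-1.57 ± 0.23), the proteoglycan Lum (-1.95 ± 0.31) and the cross-linking enzyme Lox (-1.93 ± 0.31) among them. Proliferation genes were negative in 11 of 12 (median -0.96, camera adjusted p = 6.9e-11, 0.231 with an estimated correlation), and 6 fell, including Top2a (-1.12 ± 0.16) and Mki67 (-1.21 ± 0.20). Of 11 genes of chondroitin sulphate proteoglycans and tenascins, matrix that limits axon growth, 5 fell: Ncan (-0.99 ± 0.13), Vcan (-0.73 ± 0.12), Tnc (-0.90 ± 0.17), Acan (-1.55 ± 0.33) and Tnr (-0.61 ± 0.15), with a camera adjusted p of 1.5e-06 and 0.231 with an estimated correlation. In MHC and antigen presentation 4 of 12 rose, all of class II: Cd74, H2-Aa (1.58 ± 0.17), H2-Eb1 (1.27 ± 0.19) and H2-Ab1 (1.19 ± 0.20). That list had a camera adjusted p of 7.6e-05 and 0.479 with an estimated correlation. Of the regeneration associated genes Sprr1a, the neuropeptide Gal (-2.28 ± 0.28) and Jun (-0.36 ± 0.07) fell (camera adjusted p = 0.00110, 0.479 with an estimated correlation). P2ry12 (-0.62 ± 0.11) and Tmem119 (-0.69 ± 0.13) fell among homeostatic microglia genes (0.000261, 0.479). Adjusted over the list alone, 11, 11, 6, 4, 5 and 6 members of these 6 lists passed.

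Camera set 9 further lists apart in saline. Lower at day 42 were the interferon response (adjusted p = 0.000794), where Ifi27l2a fell (-1.42 ± 0.27), cholesterol synthesis (0.00488), oligodendrocyte progenitor (0.00845), neuronal cytoskeleton (0.0114), immediate early genes (0.0114), where Jun fell, and inflammatory cytokines (0.0456), where the chemokine Cxcl9 fell (-2.17 ± 0.46). Higher were mitochondrially encoded genes (0.00488, median 0.86), oxidative phosphorylation (0.00845) and ependymal genes (0.0114). With an estimated correlation the adjusted p of these 9 lay between 0.479 and 0.732. The mitochondrial share was highest in the 2 low-share libraries of day 42, and without the 3 low-share libraries the median of the mitochondrially encoded list was 0.09 (camera adjusted p = 0.627). Ependymal (0.479), neuronal cytoskeleton (0.479) and immediate early genes (0.0682) were then not set apart either. With the long-gene share as a covariate the lists not set apart were mitochondrially encoded (0.281), ependymal (0.104), neuronal cytoskeleton (0.347) and oxidative phosphorylation (0.0554). The other 11 of the 15 lists were set apart in the same direction in each. By fry 6 of the 15 differed from no change. Lists set apart with the covariate but not over all libraries included glutamate (median 0.24, camera adjusted p = 0.000909) and postsynaptic genes (0.16, 0.000336), higher, and myelin genes (-0.23, 0.000909), lower. With an estimated correlation their adjusted p-values were 0.503, 0.397 and 0.545. Their medians were -0.07, -0.03 and -0.09 over all libraries. Without the 3 low-share libraries they were 0.22, 0.13 and -0.32, in the same direction as with the covariate.

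The genes that rose most in saline were the macrophage elastase Mmp12 (2.30 ± 0.25), the lysozyme Lyz1 (2.14 ± 0.16), Pla2g2d (2.04 ± 0.24), Cd74, H2-Aa, the cell cycle inhibitor Cdkn2a (1.51 ± 0.26), Sirpb1c (1.47 ± 0.26), the osteoclast proton pump subunit Atp6v0d2 (1.45 ± 0.19) and Syt15 (1.4 ± 0.21). The pseudogene Rps13-ps2 had no read in the 7 libraries of day 14 and was at least 288-fold higher at day 42 in saline and at least 229-fold higher in CNO, against 3 counts over the group. Lyz1 and Rps13-ps2 share sequence with near-identical copies and their counts are uncertain. Those that fell most were the imprinted RNA H19 (-4.29 ± 0.77), the collagenase Mmp13 (-4.09 ± 0.99), the macrophage gene Cd5l (-3.86 ± 0.31), Col3a1, Adamts12 (-3.17 ± 0.42), Col1a1, Sprr1a, the acute phase gene Saa3 (-2.99 ± 0.32), Colec10 (-2.89 ± 0.38) and Col8a1 (-2.68 ± 0.50). Not past the threshold were Fos (-0.06 ± 0.15), Arc (-0.16 ± 0.11), Bdnf (-0.44 ± 0.16), Rbfox3 (-0.00 ± 0.24), Gfap (0.02 ± 0.13), Mbp (0.42 ± 0.23) and Aif1 (0.12 ± 0.26), with edgeR adjusted p-values from 0.163 to 0.995. The count of 468 was 45 without the 3 low-share libraries, 40 when only the saline groups were fitted, and 1005 with the long-gene share as a covariate. It was 132, 136, 263 and 1497 without day 14 replicate 2, day 42 replicate 1, day 42 replicate 2 and day 42 replicate 3.

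From day 14 to day 42 in CNO, the same comparison in treated cords, genes of cholesterol synthesis fell together, and the collagen, proliferation and class II changes were also present. All 14 cholesterol genes were negative (median log2 -0.63) and 10 fell, including the squalene epoxidase Sqle (-0.88 ± 0.12), Cyp51 (-0.76 ± 0.13) and Lss (-0.54 ± 0.09). Camera gave an adjusted p of 1.8e-19 for this list, and 0.118 with an estimated correlation; all 14 passed adjusted over the list alone. Sprr1a fell from 78.3 ± 12.3 to 13.2 ± 2.56 CPM (SD, n = 4 and 3; -2.57 ± 0.17, edgeR adjusted p = 9.4e-06), and Gal (-2.36 ± 0.27), Jun (-0.51 ± 0.07) and the growth cone protein Gap43 (-0.50 ± 0.09) fell with it. By edgeR 60 genes rose and 233 fell of 17917, and 111 of these 293 changed by more than 1 log2 unit.

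In CNO, proliferation genes were negative in 12 of 12 (median -0.84, camera adjusted p = 2.0e-12), with Top2a (-0.97 ± 0.15), Mki67 (-1.10 ± 0.19), Mcm5 (-0.61 ± 0.12) and Ccnb1 (-1.02 ± 0.21) falling. Of 14 fibrotic scar genes 5 fell, Col3a1 (-2.65 ± 0.45), Col6a1 (-1.07 ± 0.22), Col1a1 (-2.50 ± 0.52) and Col1a2 (-1.84 ± 0.40) among them (camera adjusted p = 4.1e-09). All 14 interferon response genes were negative (median -0.91, 5.9e-09), and Ifi27l2a (-1.67 ± 0.27) and Irf7 (-1.41 ± 0.30) fell. The regeneration list had a camera adjusted p of 1.4e-11. With an estimated correlation the adjusted p-values of these 4 lists were 0.118, 0.234, 0.241 and 0.118. Adjusted over the list alone, 11, 11, 11 and 8 members passed.

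Single members also fell in other lists: the chemokine Ccl5 (-2.15 ± 0.38), Ncan (-0.97 ± 0.13), Tnc (-0.89 ± 0.16), the progenitor receptor Gpr17 (-0.68 ± 0.12), Tmem119 (-0.69 ± 0.13), the reactive astrocyte gene Timp1 (-0.79 ± 0.18) and the tubulin Tubb3 (-0.54 ± 0.11). Their lists, from cytokines to neuronal cytoskeleton, had camera adjusted p-values between 0.000145 and 0.0120, and between 0.234 and 0.596 with an estimated correlation. In MHC and antigen presentation Cd74 (1.36 ± 0.15), H2-Aa (0.96 ± 0.15) and H2-Eb1 (0.81 ± 0.18) rose. The list's mean was 0.25, its median -0.05 and its camera test positive (adjusted p = 0.0315, 0.586 with an estimated correlation). Myelin genes (median -0.32, camera adjusted p = 0.000399), heat shock genes (-0.11, 0.0455) and immediate early genes (-0.14, 0.0433) stood lower and glucocorticoid response (0.23, 0.00415) and glutamate genes (0.17, 0.0441) higher. Their adjusted p-values with an estimated correlation lay between 0.241 and 0.688. Of the 18 lists set apart by camera in CNO, 16 were set apart in the same direction with the long-gene share as a covariate. The exceptions were MHC and heat shock genes (camera adjusted p = 0.0539 each). Over all libraries 8 of the 18 differed from no change by fry. The 3 low-share libraries were all saline, so leaving them out took no sample from this comparison and could not test it. The cholesterol median was -0.63 in both fits.

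Skeletal muscle genes fell furthest in CNO: Myh2 (-7.99 ± 1.70), Ckm (-6.58 ± 1.46), Tnnc2 (-6.51 ± 1.44), Acta1 (-6.44 ± 1.42), Atp2a1 (-6.17 ± 1.4), Myl1 (-6.03 ± 1.31), Tnnt3 (-5.88 ± 1.20), Myh1 (-5.87 ± 1.29), the oxygen carrier Mb (-5.71 ± 1.26) and Tcap (-5.45 ± 1.13). Their levels rested on day 14 CNO replicate 4, with Myh2 at 108 CPM against 0.750 to 7.84 in the other 3 libraries and 0.0952 to 0.138 at day 42. The muscle list had a camera adjusted p of 1.2e-08, and 0.234 with an estimated correlation. Those that rose most were Rsc1a1 (3.88 ± 0.79), Mmp12 (2.02 ± 0.22), Lyz1 (1.85 ± 0.15), Pla2g2d (1.52 ± 0.22), Cd74, the nuclear RNA Malat1 (1.20 ± 0.22), the interferon-induced Gbp4 (1.15 ± 0.24), Cdkn2a (1.09 ± 0.25) and the imprinted RNA Kcnq1ot1 (1.07 ± 0.23), besides Rps13-ps2. Fos (-0.21 ± 0.14), Arc (-0.25 ± 0.10), Bdnf (-0.13 ± 0.14), Rbfox3 (0.07 ± 0.22), Gfap (-0.13 ± 0.12), Mbp (-0.04 ± 0.22) and Aif1 (-0.05 ± 0.25) had edgeR adjusted p-values from 0.254 to 0.969. Between the time changes in saline and in CNO, 27 rising genes were shared (0.512 would be with independent lists) and 143 falling genes (4.10 would be), and no gene was called in opposite directions. The count of 293 was 614 without the 3 low-share libraries, 865 when only the CNO groups were fitted and 1146 with the long-gene share as a covariate. Leaving out the low-share libraries, all saline, changed the shared fit but none of the samples compared here. Without day 14 CNO replicates 1, 2, 3 and 4 the count was 124, 177, 213 and 169. Without day 42 CNO replicates 1, 2 and 3 it was 53, 60 and 97.

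In the human graft at day 42, the comparison asked how the transplanted cells differed between CNO and saline. Immediate early genes, the first to respond to neuronal activity, were the list with the smallest camera p-value, with FOS at 17.8 ± 0.636 CPM in CNO and 9.42 ± 2.88 CPM in saline (SD, n = 3 each; log2 0.91 ± 0.22). NPAS4 (1.37 ± 0.36, 5.35 ± 1.11 against 2.06 ± 0.453 CPM) and NR4A1 (0.70 ± 0.19, 20.8 ± 0.941 against 12.8 ± 2.7 CPM) were also higher in every CNO table than in every saline table. None of these genes passed over all genes (edgeR adjusted p = 0.992 each). Of 14 immediate early genes tested 11 were positive (median 0.17, camera adjusted p = 0.00272, adjusted p = 0.525 with an estimated correlation). FOS, NPAS4 and NR4A1 passed adjusted over the list alone, and ARC had a log2 of -0.01 ± 0.25.

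**Figure D4:**
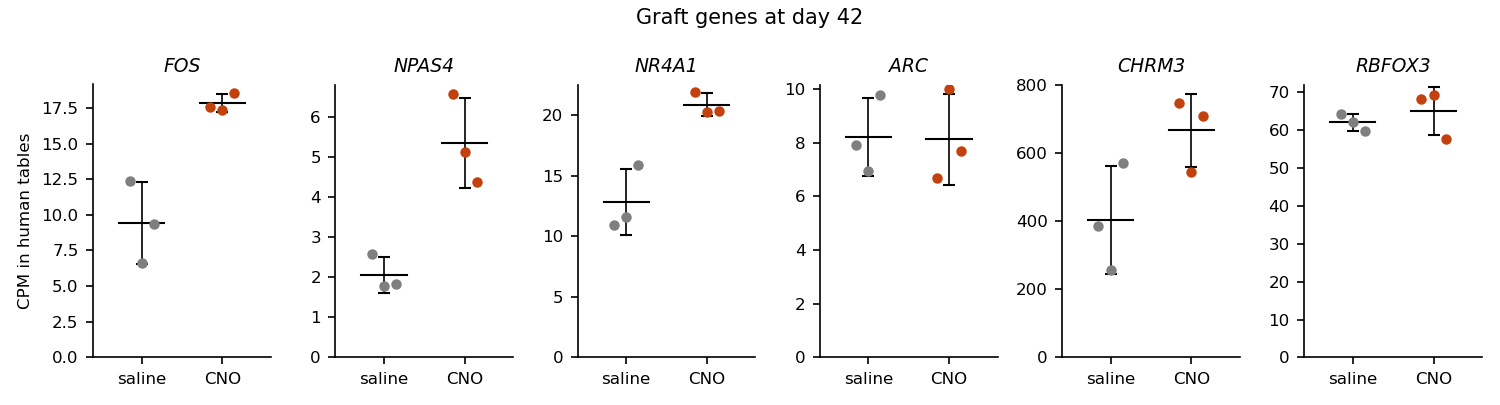
CPM of 6 genes in the human tables of day 42, saline and CNO; dots are samples, horizontal lines are means and bars are the SD (n = 3 each). FOS lay between 17.3 and 18.5 CPM in CNO and between 6.60 and 12.4 in saline, while ARC and RBFOX3 overlapped.

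Of the other graft lists, camera set apart as higher voltage-gated ion channels (12 of 13 positive, median 0.19, adjusted p = 0.00734), axon growth and guidance (12 of 13, 0.17, 0.0154), oligodendrocyte lineage (6 of 7, 0.34, 0.0154), presynaptic release (11 of 16, 0.17, 0.0238), postsynaptic scaffold (13 of 14, 0.11, 0.0328), and muscarinic receptors and Gq calcium signalling (10 of 11, 0.08, 0.0421). Set apart as lower were proliferation (11 of 12 negative, -0.28, 0.00734), mitochondrially encoded genes (12 of 12, -0.25, 0.0101), spinal and hindbrain patterning (10 of 13, -0.10, 0.0388), oxidative phosphorylation (9 of 13, -0.13, 0.0421), and heat shock genes (8 of 12, -0.11, 0.0421). With an estimated correlation the adjusted p of all 12 lists lay between 0.525 and 0.613, fry set 0 apart (from 0.591), and outside the immediate early genes no member passed adjusted over the list alone. Members with small p-values included KCNC1 (0.42 ± 0.17), UNC5C (0.43 ± 0.17), CENPA (-1.43 ± 0.45) and HOXC6 (-0.43 ± 0.14). Immediate early genes stayed set apart with each table left out in turn (median 0.12 to 0.25, camera adjusted p from 0.000120 to 0.0274) and with the long-gene share as a covariate (0.0106), but not with an estimated correlation in any of these fits (adjusted p from 0.345 to 0.894). The proliferation list rested on saline replicate 3: without it the median was 0.06 (camera adjusted p = 0.966), and without CNO replicate 2 it was -0.15 (0.0986). MKI67 was at 68.5 CPM in that saline table, at 21.4 and 20.8 in the other saline tables and at 23.5 to 38.3 in CNO. With the covariate proliferation was set apart lower (0.0111) and the other 10 lists were not set apart, while mesenchymal genes stood higher (0.0240). Without the graft tables of the 2 low-share libraries, 3 CNO tables were set against saline replicate 3 alone. The spread then came from the CNO tables alone, and the lists followed that saline table, so their values are not given. The muscarinic receptor CHRM3 was at 666 ± 108 CPM in CNO and 403 ± 159 in saline (0.72 ± 0.24, unadjusted p = 0.0108 by edgeR across the tables, adjusted p = 0.992).

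Over all 16030 tested graft genes edgeR called 4, 1 higher and 3 lower, all named only by an Ensembl transcript identifier, with 416 at an unadjusted p below 0.05; DESeq2 called 7. The higher one, ENST00000608591.5, had 101 reads in CNO and 0 in saline, at least 30.4-fold higher against 3 counts over the group. The transcript ENST00000609365.2 had 106 reads in saline and 0 in CNO, at least 39.1-fold lower. These transcripts fall outside the rule for named genes and were chosen after their values were seen. The smallest p-values among named genes belonged to the sodium leak channel partner UNC80 (0.76 ± 0.17), FOS, NPAS4, NR4A1 and TMEM132D (0.66 ± 0.18) among positive values. Among negative values they belonged to TMEM160 (-0.64 ± 0.16), TCTEX1D1 (-0.96 ± 0.27), the histone pseudogene H3P6 (-2.90 ± 0.84, uncertain for its near-identical copies), FAM156B (-1.15 ± 0.34, likewise) and GGT1 (-2.02 ± 0.60). MKI67 (-0.25 ± 0.38), RBFOX3 (0.07 ± 0.13), GFAP (0.13 ± 0.41) and BDNF (0.05 ± 0.38) had edgeR adjusted p-values from 0.992 to 0.996. Human reads per 100 mouse reads were 22.0 ± 2.67 in CNO and 23.9 ± 1.04 in saline (two-sided exact permutation p = 0.300; the smallest that 3 against 3 can give is 0.1). The count of 4 was 0 without saline replicate 2, saline replicate 3, or the transcript-named entries, 1 without saline replicate 1, 2 without CNO replicate 2, 6 without CNO replicate 1 and 4 without CNO replicate 3.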

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

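The tests of long-gene share in the host, host reads in the graft tables, read allocation and other splits of the samples were chosen after the results were seen, while the tests of library depth and of long-gene share for the graft's early genes were set out before.

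The 1395 host genes called for CNO averaged over days ran with the make-up of the libraries, as all 3 low-share libraries were saline. Thinning every library to 17479400 reads, the lowest total, left 1107 of them past the threshold. Their median fold change stayed at 1.00 times its size, but random thinning keeps the proportions of each library. The test therefore cannot decide on differences in make-up that go with depth. Without the 3 low-share libraries the median fold change in the called direction went from 0.42 to 0.25 (0.586 times; 0.431 to 0.728 leaving out a further library), all 1395 kept their direction and 0 were called, with 1 saline library left at day 42; with the share as a covariate it was 0.19 (0.455 times) and 1393 kept their direction. A lower long-gene share in saline libraries, from RNA quality or from the tissue itself, and an effect of CNO or of the stimulated graft on the host cannot be told apart, since the share and the treatment overlap in this design. Of 100 splits drawn at random, 1 (the real one, 1395 genes) was as large and the highest other gave 1 gene. The draw missed 2 splits that called more genes than the real one, so it does not exclude chance. Of all 700 splits, 11 others had a larger difference in long-gene share than the real 2.78 points. Outside the draw, 2 of these, with the largest differences (3.26 and 3.25), called 4742 and 3157 genes, more than the real 1395. Each exchanged day 14 saline replicate 3 with 1 CNO library, as did a split at 2.95 that called 0, and that saline library was among the CNO side in all 11. In all, 9 splits (2.80 to 3.11) called 0 by edgeR, with 3761 to 6232 genes at an unadjusted p below 0.05 against 6849 in the real one; DESeq2 was not run on splits. These splits go both ways, and the real count lies close to the threshold (smallest edgeR adjusted p 0.0467). Chance, the share and the treatment stay open.

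In the graft, FOS, NPAS4 and NR4A1 were higher in CNO by a mean log2 of 0.99. With the long-gene share as a covariate, over all 6 tables, their mean was 0.995 times as large (FOS 0.81 ± 0.23, NPAS4 1.47 ± 0.37, NR4A1 0.68 ± 0.20), which argues against the share. Without the 2 graft tables of low-share libraries it was 0.961 times, with NR4A1 at 0.39 ± 0.23, but this leaves a single saline table, with the spread taken from the CNO tables alone. On 12 host-only genes together fell 93 human against 484966 mouse reads (0.0192%). At this pooled rate, host reads of the 3 early genes counted as human would make up 0.165% of the difference of 161 reads per table. The rate differed between host-only genes, from 0 human against 161387 mouse reads on C1QA to 29 against 7519 on CLDN5. It was not measured for FOS, NPAS4 or NR4A1 themselves. An effect of CNO on the graft stays open and untested beyond this comparison, in which none of the 3 genes passed over all genes and ARC had a log2 of -0.01 ± 0.25.

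The 4 transcripts called in the graft were read in every table of one group and absent from the other. By the real grouping 6 transcripts had at least 10 counts in each table of one group and 0 in the other, and the highest other split of the 6 tables gave 5. Such transcripts thus appeared under other groupings too, which does not show what produced them. Allocation of reads among near-identical transcripts stays a candidate explanation that this count cannot decide. No biological explanation was tested for them.

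Other splits of the samples decide nothing where the real count was 0, since no split can give fewer. This held for CNO at day 14 (0 edgeR genes, 2479 at an unadjusted p below 0.05, DESeq2 111; 35 splits, highest other 2), for CNO at day 42 (0 edgeR genes, 5480 unadjusted, DESeq2 1398; 10 splits, highest other 0) and for the interaction (0 edgeR genes, 901 unadjusted, DESeq2 11; 100 splits). The highest other split of the interaction gave 3157 genes, the count that a split of the averaged comparison also gave. Exchanging all CNO and saline labels of day 42 alone turns the interaction contrast into the averaged one, apart from sign and scale. Both counts can therefore come from the same test, and 3157 need not reflect a CNO effect that changed between days. Time in CNO had 1 of 35 splits as large, the real one with 293 genes, and the highest other gave 23. That share, 0.0286, is the smallest that 35 splits can give, so chance is unlikely but not excluded. For time in saline and the graft, 10 splits are too few for a share under 0.05. In the graft 2 of 10 splits were as large, the real count being 4 and the highest other 6. Time in saline gave 468 and 2 of 10 splits as large; the highest other, 4873, set the 3 low-share libraries against the other 3 and so follows the structure of the samples.

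Among the 4 CNO libraries of day 14, 15 of 70 values tested lay far from the rest of their group, measured as the gap to the nearest library over the range. Chance passes Dixon's critical value, the limit used, in about 1 of 20 groups. That rate is for independent genes not chosen by these values. The muscle genes below varied together and were named for their fall from day 14 in CNO, so it does not apply to them. Replicate 4 was highest for the muscle genes Acta1 (0.909, 320 against 3.15 to 31.8 CPM), Atp2a1 (0.934), Ckm (0.871), Mb (0.890), Myh1 (0.882), Myh2 (0.934), Myl1 (0.928), Tcap (0.865), Tnnc2 (0.846) and Tnnt3 (0.881), and lowest for Msx2 (0.918, 0.691 against 1.75 to 1.85 CPM). Ctla2b stood highest in replicate 1 (0.860, 8.86 against 6.32 to 6.68 CPM). Gbp4 stood highest in replicate 3 (0.847, 3.72 against 2.30 to 2.52 CPM) and Mbp lowest there (0.830, 10187 against 12273 to 12701 CPM). Rsc1a1 was read in replicate 2 only (1, 1.05 CPM against 0).

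The CNO effect differed between days by the interaction test of camera in 11 lists, none with an estimated correlation (adjusted p = 0.839 each) or by fry. Of these 11, 7 were not set apart by camera without the 3 low-share libraries: the median of MHC genes went from -0.34 to -0.03 (camera adjusted p = 0.771), of mitochondrially encoded genes from -0.62 to 0.17 (0.190) and of ion channels from 0.32 to 0.02 (0.886). With the share as a covariate 7 were not either, with medians of -0.11, 0.06 and -0.15 for these 3. Adjusted p-values were 1.9e-10 for cholesterol synthesis, 1.1e-05 for skeletal muscle, 0.00178 for oxidative phosphorylation, 0.00306 for MHC and antigen presentation, 0.00477 for fibrotic scar, 0.00627 for voltage-gated channels, 0.0139 for heat shock, 0.0139 for mitochondrially encoded genes, 0.0146 for regeneration associated genes, 0.0160 for GABA and glycine signalling and 0.0212 for myelin.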

How the results depend on the processing

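Alternatives without the low-share libraries, with the long-gene share as a covariate, with effective lengths, with gene-named graft entries, graft lists with 1 table left out, and the estimated correlation in these fits were chosen after the data were seen; the cause was not tested for any difference, except that fewer samples or entries enter some fits. The pseudocount alternative was not run. Correlations between samples of equal number ran from -0.15 to 0.46. The best match had the same number for every host pair of CNO and saline at day 42, and for no pair of CNO libraries between days. Whether sample numbers pair samples is therefore not settled.

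DESeq2 called 111 genes at day 14, 1398 at day 42, 4160 averaged, 11 for the interaction, 965 for time in saline, 763 for time in CNO and 7 in the graft. The averaged count was 13 with DESeq2's size factors, 2118 without a filter, 2470 with the stricter filter, and 0 with the replicate block, the letter block, the covariate, effective lengths, or without the 3 low-share libraries (edgeR; 6849 at an unadjusted p below 0.05 in the reported fit, DESeq2 4160). At day 14 the replicate block gave 4. Time in saline gave 40 with only the groups compared, 45 without the low-share libraries, 1005 with the covariate and 249 with effective lengths. Time in CNO gave 865, 614, 1146 and 118 in the same order, 188 with the replicate block and 82 with the letter block. The graft gave 123 without a filter, 7 with either block, 2 without 2 tables, and 0 with the covariate or gene names only (edgeR; 416 unadjusted, DESeq2 7). Leaving out 1 library gave 0 to 5 genes at day 14, 0 to 5688 at day 42, 0 to 6725 averaged, 0 to 3 for the interaction, 132 to 1497 for time in saline, 53 to 213 for time in CNO and 0 to 6 in the graft. With an estimated correlation camera set apart no list of any comparison over all libraries, without the low-share libraries or with the covariate, except host immediate early genes averaged over days with the covariate (adjusted p = 0.0418).

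Log2 values of these genes changed sign. With DESeq2 they were Bdnf 0.0027 averaged. With DESeq2's size factors they were Bdnf 0.0037 averaged. Without a filter they were Bdnf 0.021 averaged, Gfap -0.0058 for time in saline. With the replicate block they were Bdnf 0.016 averaged. With the letter block they were Gfap 0.0043 at day 14, Aif1 0.17 and Mbp 0.052 for time in CNO. Without the 3 low-share libraries they were Arc -0.052 averaged, Fos 0.025, Bdnf -0.039, Arc -0.14 and Col1a1 -0.35 at day 42, Mbp 0.12, Fos 0.095, Aif1 0.17 and Rbfox3 -0.17 for the interaction, Mbp -0.15, Aif1 -0.22, Gfap -0.0085, Rbfox3 0.25 and Il1rn -0.036 for time in saline. Without 2 graft tables they were GFAP -0.57, BDNF -0.14, MT-ND5 0.079, MT-ATP8 0.11, UQCRB 0.025, BSN -0.074 and HOXA5 0.0020 in the graft. With the covariate they were Arc -0.050, mt-Co3 0.052, mt-Nd3 0.090, Ltf -0.20, Mobp 0.022 and Mog 0.0086 averaged, Mbp 0.0045 at day 14, Aif1 0.15, Arc -0.15, Col1a1 -0.45, mt-Co3 0.046 and Pcna 0.011 at day 42, Aif1 0.35 and Rbfox3 -0.28 for the interaction, Aif1 -0.31 (edgeR adjusted p = 0.0462), Gfap -0.043 and Rbfox3 0.30 for time in saline, Aif1 0.036 and Mbp 0.030 for time in CNO, BDNF -0.077 in the graft. With effective lengths they were Bdnf 0.022 averaged, Arc -0.026 at day 42, Aif1 0.081 for time in CNO, MKI67 0.16 in the graft. Leaving out 1 library the ranges were Bdnf -0.071 to 0.042 and Col1a1 -0.61 to 0.0042 averaged, Arc -0.041 to 0.099 and Col1a1 -0.073 to 0.30 at day 42, Aif1 -0.43 to 0.19, Fos -0.28 to 0.023 and Rbfox3 -0.18 to 0.33 for the interaction, Aif1 -0.24 to 0.38, Fos -0.24 to 0.068, Gfap -0.097 to 0.11 and Rbfox3 -0.26 to 0.25 for time in saline, Aif1 -0.13 to 0.029 for time in CNO, ARC -0.19 to 0.13, BDNF -0.20 to 0.29, GFAP -0.56 to 0.68, MKI67 -0.54 to 0.55 and MT-ATP8 -0.47 to 0.0042 in the graft, where the median of the proliferation list ran from -0.49 to 0.063. Of all values of named genes with 1 library left out, 2457 kept direction and side of the threshold, 825 no longer passed, 104 newly passed, and 35 changed sign.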

Other observations

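In the human tables the muscarinic receptor CHRM3 had a mean of 534 CPM, rank 164 of 14604 gene-named entries. CHRM2 had a mean of 26.6 CPM (rank 7670), CHRM4 of 2.95 and CHRM5 of 2.15. The labels name chemogenetic stimulation but not the receptor, and whether reads of an introduced receptor derived from one of these genes are counted there was not tested.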
